A study of Homo sapiens with 8 samples.

How the data were processed

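Expression was measured in LNCaP and DU145 prostate cancer cells, each transfected with a negative control miRNA (nc), miR-29b, a control siRNA (siControl) or an siRNA against TET2 (siTET2). Per the labels' protocols, the cells grew in RPMI medium with 10% fetal bovine serum, total RNA was extracted with ISOGEN 72 hours after transfection, and the RNA was labelled with biotin by the Affymetrix whole transcript kit. There were 8 arrays, 1 per cell line and construct, so no group has a replicate. Nothing in the sources used here says on which day a dish was grown or an array was run.

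The authors deposited 1 table of log2 expression values for 33297 probe sets and 8 arrays. Per the submitters' processing notes, Affymetrix Expression Console and RMA made these values. RMA corrects the background, applies quantile normalization and summarises probes as log2 values, but the table itself states no log base and not which arrays were normalized together. The medians over all probe sets were 7.17 (nc), 7.14 (miR-29b), 7.10 (siControl) and 7.12 (siTET2) in LNCaP, and 6.59 (nc), 6.66 (miR-29b), 6.62 (siControl) and 6.62 (siTET2) in DU145. Levels were therefore compared within a line only, and a difference between 2 arrays is called a log2 difference on the reading that the deposited values are on the log2 scale. No value was missing.

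Gene names came from the platform's annotation and were checked through Entrez identifiers against RefSeq's gene table, which changed 0 symbols. Of the probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed. Of those with 1 symbol, 19429 matched RefSeq and 31 kept the annotation's symbol. Probe sets with several symbols were not named. This left 18417 genes. For the 769 genes with several probe sets, the probe set with the highest mean over the 8 arrays stood for the gene. Some well-known genes of these lines and pathways were not analysed here.

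The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Each of 4 contrasts was the difference of 2 arrays of a line: miR-29b minus nc and siTET2 minus siControl, in LNCaP and in DU145. Such a contrast has no p-value. Genes were counted at a log2 difference of at least 1 (2-fold) among those above a level floor, which required the higher of the 2 arrays to reach that array's 50th percentile over named genes. The difference between the control arrays of a line (siControl minus nc) was counted the same way as background. It holds the difference between both control constructs as well as that between dishes and arrays.

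Effects common to both lines were tested with limma (lmFit and eBayes) on all 8 arrays, with cell line and construct as terms and 3 residual degrees of freedom. The spread in this fit is the departure of each array from the same construct effect in both lines. It was run on the 9209 genes whose mean over the arrays was at or above the median of such means, with Benjamini-Hochberg adjustment and a threshold of 0.05. The words rose, fell and changed are used only for genes that passed this test over all genes or, where the text says so, with the adjustment over a gene list alone. The labels name no separate cultures behind these arrays, so the p-values measure the spread between these arrays, which may be technical in part.

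There were 30 gene lists, written from textbook knowledge. They cover miR-29 targets (extracellular matrix and other), DNA methylation enzymes, androgen-induced and androgen-repressed genes, S phase and G2/M genes, p53 targets, the BCL2 family, interferon response, unfolded protein and ATF4 response, cholesterol and lipid synthesis, epithelial and mesenchymal markers, snoRNA and histone cluster genes, and further pathways. Marker lists of LNCaP, DU145, immune cells and fibroblasts were included as a check of the cells. For each contrast, the median difference of a list's members above the floor was set among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was called apart at or below the 2.5th or at or above the 97.5th percentile. Lists needed 5 members above the floor. This percentile describes these arrays and is no test of the treatment. In the common fit, lists were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated and with fry.

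The genes named in the text are TET1, TET2, TET3, DNMT3A and DNMT3B, the 10 protein-coding genes with the largest positive and the 10 with the largest negative difference of each contrast, the 10 with the largest rise and the 10 with the largest fall shared by both lines, and up to 4 members of each list with the largest absolute difference. A name outside this rule is marked where it stands.

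The scripts were tested on simulated data. For siTET2 minus siControl in the common fit, over 9209 genes, limma recovered 82% of 100 genes changed by 1 log2 unit and 2% of 100 changed by 0.5, with 10 false calls. It called 0 genes in a simulated contrast with no change. For DU145 siTET2 minus siControl, over 9424 genes, the list procedure called 8% of 200 lists of 30 genes that had no shift, 68% of those shifted by 0.1 and 99.5% of those shifted by 0.2.

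The alternatives were the line's other control array, the mean of both control arrays, quantile normalization of the 8 arrays, loess centring of each contrast (span 0.4), no level floor, a floor at the 75th percentile, the mean of a gene's probe sets, and a 1.5-fold threshold. For the common fit they were eBayes with a trend, no term for cell line, only the 4 arrays of a contrast, and each array left out in turn. A planned search for miR-29 seed sites was not run, since no 3' UTR sequence was used here. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The number of arrays limits the precision of every value.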

Results

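Transcript levels were measured on 8 arrays, 1 for each of 4 constructs in each of 2 prostate cancer cell lines. LNCaP is an established line that responds to androgen and makes prostate-specific kallikreins, and DU145 is an established line that grows without androgen. Each line received a negative control miRNA (nc), miR-29b, a control siRNA (siControl) or an siRNA against TET2 (siTET2), and RNA was taken after 72 hours. TET2 is an enzyme that oxidises methylated cytosine in DNA, and miR-29b is a microRNA of a family known to repress collagen genes and enzymes of DNA methylation. The marker genes of each line matched its label. Of 10 LNCaP markers, 9 or 10 lay above the array's median in each LNCaP array and 1 in each DU145 array. Of 13 DU145 markers, all 13 lay above it in each DU145 array and 2 in each LNCaP array. Of 12 immune cell markers, 1 lay above the median in every array, and of 10 fibroblast markers, 0 or 1 did. No group had a replicate, so the contrasts within a line are given as values with no p-value.

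TET2, the gene that both treatments address, was lowest in the siTET2 array of each line. In LNCaP its log2 value was 9.01 with siControl and 7.89 with siTET2, a difference of -1.12 or 2.17-fold. In DU145 it was 7.85 with siControl and 6.60 with siTET2, a difference of -1.25 or 2.37-fold. With miR-29b, TET2 was 8.59 against 9.24 with nc in LNCaP (-0.64) and 7.79 against 7.96 in DU145 (-0.18). The gene's other probe set, of lower mean level, gave -0.85 and -0.91 for siTET2 and -0.34 and -0.07 for miR-29b, in LNCaP and DU145. The control arrays of a line differed in TET2 by -0.23 in LNCaP and -0.11 in DU145 (siControl minus nc). TET3, a related enzyme, was lower with miR-29b (-0.63 in LNCaP and -0.26 in DU145), and differed by -0.25 and 0.16 with siTET2. TET1 was 0.81 higher with siTET2 in DU145, where siControl lay -0.35 from nc, and its probe set lay below the array's level floor in every LNCaP array and in the other 3 of DU145. The DNA methyltransferases DNMT3A and DNMT3B, both known miR-29 targets, differed by -0.13 and -0.04 with miR-29b in LNCaP and by 0.01 and 0.15 in DU145, with DNMT3B's probe set below the level floor in all 8 arrays. Against the line's other control array, TET2 with miR-29b was -0.41 in LNCaP and -0.06 in DU145, and TET1 with siTET2 in DU145 was 0.46. DNMT3A in LNCaP was 7.85 with miR-29b, below nc (7.97) but above siControl (7.76). DNMT3B in DU145 was 7.24 with miR-29b, 7.09 with nc and 6.86 with siControl.

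**Figure D1:**
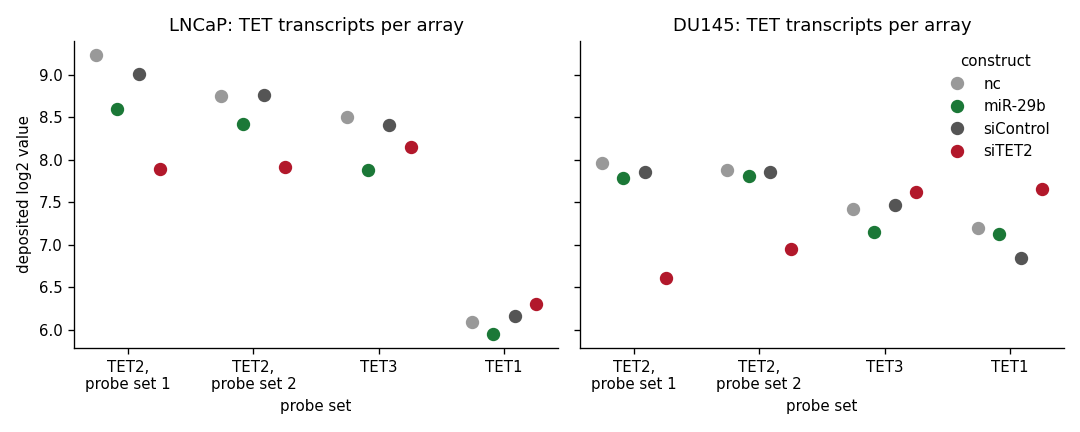
Deposited log2 value (vertical axis) of the TET2, TET3 and TET1 probe sets (horizontal axis) in each array, for LNCaP on the left and DU145 on the right, with 1 point per array coloured by construct. In both lines the siTET2 array has the lowest TET2 value, 7.89 in LNCaP and 6.60 in DU145 for the probe set that stands for the gene.

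The effect of siTET2 common to both lines was asked with limma over all 8 arrays. TET2 fell by 1.18 on the log2 scale (SE 0.124, limma adjusted p = 0.0178). Along with it fell METAP2, a methionine aminopeptidase (-1.19, SE 0.128), SKAP2, an adaptor of Src kinases (-1.19, SE 0.13), OTUD6B, a deubiquitinase (-0.92 in LNCaP and -1.08 in DU145, SE of the common effect 0.102), and PERP, a desmosome protein (-1.26, SE 0.156). These 4 had limma adjusted p-values from 0.0178 to 0.0250. Only 1 construct against TET2 was used, so effects of losing TET2 cannot be told apart from other effects of this siRNA. In all, 32 genes fell and 3 rose among 9209 tested, and 1266 had an unadjusted p below 0.05. The 3 that rose were YPEL2 (0.76), TP53INP1, a p53-induced regulator of cell death (0.62), and CD274, the immune checkpoint ligand PD-L1 (0.61). RNF13 (-0.95), AKTIP (-1.15), TMEM38B (-0.85) and TMEM19 (-0.85) fell as well. SCD, the desaturase of fatty acids, was lower in both lines (-0.98 in LNCaP, -1.67 in DU145), but its common difference of -1.33 had an SE of 0.350 and a limma adjusted p of 0.161. The same fit of siControl minus nc gave 0 genes with limma, with 1212 at an unadjusted p below 0.05.

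Genes of cell division formed the largest group lower with siTET2. Of 39 G2/M genes tested, the median common difference was -0.41, and 32 fell when limma's p was adjusted over the list alone, against 1 (CDK1, the mitotic kinase, -0.83, limma adjusted p = 0.0211) over all genes. Of 37 S phase genes the median was -0.36, with 24 that fell adjusted over the list alone and 0 over all genes. Histone cluster genes had a median of -0.32, with 15 of 33 that fell and 1 that rose adjusted over the list alone, against 1 that fell (H2BC14, -0.84) over all genes. Targets of p53 had a median of 0.18, with 5 of 25 that rose and 1 that fell adjusted over the list alone, against 1 that rose over all genes. LNCaP has wild-type and DU145 mutant p53, and whether p53 acted on these genes was not tested. Mesenchymal markers had a median of 0.13, with 3 of 15 that rose adjusted over the list alone and 0 over all genes. With the preset correlation, limma's camera called 7 of 28 lists, the other 2 being lipid synthesis (-0.11) and extracellular matrix targets of miR-29 (0.17). With an estimated correlation it called 0 of 28, with adjusted p = 0.450 for G2/M, histone, p53, mesenchymal and matrix target genes, adjusted p = 0.482 for S phase and adjusted p = 0.744 for lipid synthesis, and fry called 0. For siControl minus nc, camera at the preset correlation called 1 list, the G2/M genes, with a median of 0.15 (adjusted p = 0.934 with an estimated correlation). The calls of single genes rest on few arrays: limma called 0 genes without LNCaP siControl, DU145 siControl or DU145 siTET2, 10 without LNCaP nc, 11 without either miR-29b array, 28 without DU145 nc, and 132 without LNCaP siTET2. With no level floor the fit called 1 gene, which was not among the 35, without the term for cell line 0, with nc as the control 18, with the stricter floor 87 (22 of them among the 35) and with a trend 113.

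**Figure D2:**
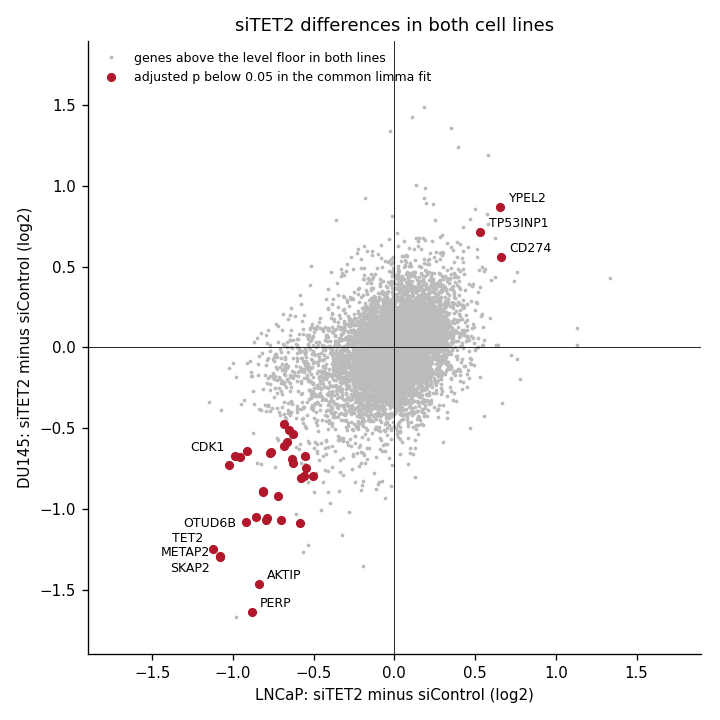
Log2 difference of siTET2 minus siControl in LNCaP (horizontal axis) and in DU145 (vertical axis), with a grey point for each of the 8300 genes above the level floor in both lines and a red point for each of the 35 genes called in the common limma fit. The red points lie in the lower left for the 32 genes that fell and in the upper right for YPEL2, TP53INP1 and CD274.

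In LNCaP, the siTET2 array differed from siControl above all in the cell cycle. The 39 G2/M genes had a median of -0.67, below that of every random list, and all 39 were below 0. CDK1 (-0.99), CENPE, a kinetochore motor (-0.95), ECT2 (-0.90) and ASPM (-0.88) differed most. S phase genes had a median of -0.54, with MCM10 (-0.87), CCNE2, a cyclin of the G1/S transition (-0.85), POLE2 (-0.79) and GINS1 (-0.79) in front. Histone cluster genes had a median of -0.41. Targets of p53 were higher, with a median of 0.30, led by CDKN1A, the inhibitor of cyclin-dependent kinases (0.74), and ZMAT3 (0.72). Androgen-induced genes had a median of 0.10, androgen-repressed genes 0.23, LNCaP markers 0.12 and interferon-response genes 0.16. Lipid synthesis genes had a median of -0.16, with SCD at -0.98, and cholesterol synthesis genes -0.10, which was 0.07 against nc. Set against nc, the named cell cycle genes were closer to 0, with CDK1 at -0.40, CENPE at -0.20, ECT2 at -0.25, ASPM at -0.44, CCNE2 at -0.32 and POLE2 at -0.21, as were the medians of S phase (-0.32), histone cluster (-0.26) and lipid synthesis genes (-0.10), whereas ZMAT3 was at 1.15 and the interferon median at 0.24. The median of androgen-repressed genes was 0.10 with no floor, inside the range of random lists, and that of p53 targets 0.19 with the stricter floor.

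By single genes, 5 were at least 2-fold higher and 9 at least 2-fold lower among 9422 genes in LNCaP. The higher ones were SNAI2, a transcription factor of epithelial-mesenchymal transition (1.34), GRIN3A (1.31), AHNAK2 (1.13), OLFM2 (1.13) and CHRNA2, an androgen-induced gene (1.02). The lower ones included ADD3 (-1.15), TET2, AKR1C2, an enzyme of steroid metabolism (-1.10), METAP2 (-1.08) and SKAP2 (-1.08). UGT2B17, which inactivates androgens, was -1.06 from siControl but 0.28 from nc. Against nc, 9 genes were at least 2-fold higher and 4 lower, and against the mean of both controls 2 were lower; with the stricter floor 3 were higher, and with no floor 15 were lower. From nc, OLFM2 was at 0.45, METAP2 at -0.62 and SKAP2 at -0.69. The control arrays of LNCaP differed by at least 2-fold in 13 genes, all higher with siControl. Their G2/M median differed by 0.33, so that the G2/M median of siTET2 was -0.34 when set against nc. Of 27 lists, 14 stood apart from random lists with siTET2 and 9 between the control arrays. The threshold alone would give 1.35 if genes varied independently. Members of a list can vary together (correlation of 0.745 estimated for G2/M genes in the common fit), so 1.35 is too low a background for such lists. Of the 14, 8 stood apart in the same direction against nc, where 9 lists stood apart in all.

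In DU145, more genes differed at least 2-fold between siTET2 and siControl than between the control arrays. The higher genes were led by LIPH, a phospholipase (1.49), TRAF1, an adaptor of TNF receptors (1.47), HMOX1, the oxidative stress enzyme heme oxygenase (1.43), TXNIP, a regulator of thioredoxin and glucose uptake (1.36), IL6R (1.34) and SESN2, a stress-induced inhibitor of mTOR (1.24). The lower genes were led by SCD (-1.67), PERP (-1.64), AKTIP (-1.47), THOC7 (-1.35) and SKAP2 (-1.30). In all, 12 genes were at least 2-fold higher and 20 at least 2-fold lower among 9424, against 4 and 0 between the control arrays of DU145; 20 were higher when set against nc, and 4 with the stricter floor. Unfolded protein and ATF4 genes had a median of 0.07, with 18 of 33 above 0 and SESN2, CHAC1 (0.92) and DDIT3 (0.81) highest, whereas the same list had a median of -0.12 in LNCaP, with SLC7A11 at -0.98. Against nc, the LNCaP median was -0.0091 and SLC7A11 was at -0.39, and against the mean of both controls the DU145 median was 0.04, inside the range of random lists. G2/M and S phase genes both had a median of -0.15, with CDK1 at -0.67 and HMMR at -0.57, and histone cluster genes -0.22. Lipid synthesis genes had a median of -0.17, and FASN, the fatty acid synthase, was at -0.52. Mesenchymal markers were at 0.11, with ITGA5 at 0.92 and TGFBI at 0.58, and BCL2 family genes at 0.13. Targets of p53 had a median of 0.17, which was -0.05 with the stricter level floor. SCD also differed between the control arrays (-0.93, siControl minus nc), so that siTET2 was -2.60 from nc. Also against nc, DDIT3 was at 1.72, FASN at -1.13, CDK1 at -0.29 and TGFBI at 0.22, and the medians were -0.40 for histone cluster, -0.35 for lipid synthesis and 0.02 for BCL2 family genes. With no floor the histone cluster median was -0.12. Of 27 lists, 12 stood apart with siTET2 and 7 between the control arrays, and 8 of the 12 stood apart in the same direction against nc.

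The siTET2 differences of both lines were compared across genes. The 8300 genes above the floor in both lines gave a Pearson r of 0.39 and a Spearman rho of 0.35 across genes, which are not independent replicates; with no floor r was 0.24. METAP2, SKAP2 and TET2 were at least 2-fold lower in both lines, 3 genes where independent lists would share 0.0160. At 1.5-fold, a threshold added to this comparison after the data were seen, 32 genes were lower in both lines against 2.92 for independent lists, and 2 (PLAGL2 and YPEL2) were higher in both against 0.113.

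The question of the miR-29b contrast was what the microRNA changed in each line, and in LNCaP the largest differences were in interferon-stimulated genes. IFIT2 was 6.15-fold higher than with nc (log2 2.62) and IFIT1 3.78-fold (1.92), both being antiviral proteins that bind foreign RNA. The chemokines CXCL8 (1.38), CXCL10 (1.22) and CCL5 (8.86 against 7.86) and the interferon-induced genes OASL (1.20), IFI6 (1.17) and DTX3L (1.13) were also higher. Against siControl, DTX3L was at 0.22, IFI6 at 0.58 and CCL5 at 1.71, as siControl lay 0.91, 0.59 and -0.71 from nc. The interferon list had a median of 0.68 over 19 genes, above every random list. The floor took the higher of the 2 arrays, so IFIT1 and IFIT2, among others, entered only through their miR-29b value. Of 39 members measured, 15 passed the floor between the control arrays. In DU145 the list's median with miR-29b was -0.14 over 13 genes, at percentile 3.68 of random lists. It lay further below siControl than below nc. Set against each gene's mean over the line, the medians of these 13 genes were -0.22 with miR-29b, -0.08 with nc and 0.13 with siControl.

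**Figure D3:**
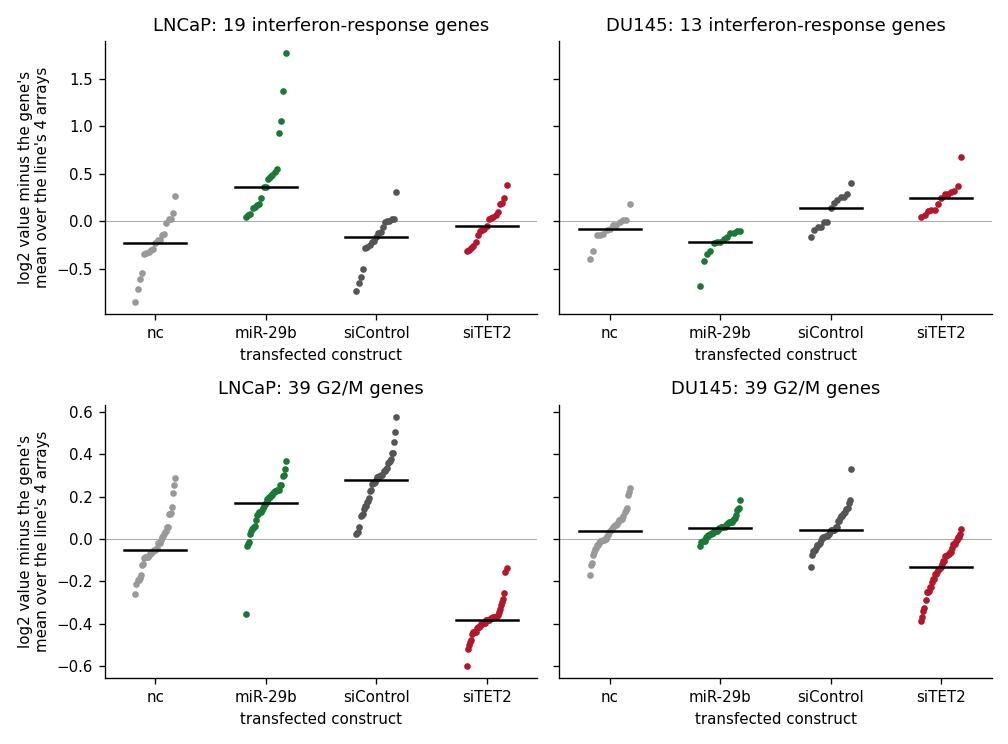
Log2 value minus the gene's mean over the 4 arrays of its line (vertical axis) for each construct (horizontal axis), with interferon-response genes in the upper and G2/M genes in the lower panels, 1 point per gene above the level floor and a black line at the median. In LNCaP the interferon median is 0.36 with miR-29b and between -0.23 and -0.05 in the other arrays, and the G2/M median is -0.38 with siTET2 and between -0.05 and 0.28 in the others.

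Known targets of miR-29 were lower in LNCaP. The list of targets outside the matrix had a median of -0.21 over 32 genes, 26 of them below 0, with MYBL2, a transcription factor of the cell cycle (-0.64), TRAF4 (-0.60) and KDM5B, a histone demethylase (-0.56), and with TNFAIP3 at 0.47. Extracellular matrix targets had a median of -0.16 over 5 genes, all 5 below 0, with LAMC1 at -0.35 and PXDN at -0.34. The largest negative differences were POMK (-0.87), PRMT6, an arginine methyltransferase (-0.83), MMP15 (-0.79) and HOMER2 (-0.79). Androgen-induced genes had a median of -0.20, with HPGD (-0.67), TRPM8 (-0.50) and SLC45A3 (-0.48) lowest, and LNCaP markers had a median of -0.20. The BCL2 family had a median of -0.13, with BAK1 at -0.62 but PMAIP1, which promotes cell death, at 0.87. Epithelial markers were at -0.11 and mesenchymal markers at -0.15. Unfolded protein and ATF4 genes had a median of 0.21, with CHAC1 at 0.99 and SLC7A11 at 0.74, and p53 targets a median of 0.13, with ZMAT3 at 0.77. With the stricter floor the p53 median was 0.04, inside the range of random lists, and with the mean of both controls that of unfolded protein and ATF4 genes was 0.12. S phase genes were at 0.18 and G2/M genes at 0.20.

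In total 9 genes were at least 2-fold higher and 0 at least 2-fold lower among 9444 in LNCaP, against 13 and 0 between its control arrays. With no floor 17 were higher and 1 lower, with the stricter floor 2 were higher, and against siControl 1 was lower. Against siControl in place of nc, the interferon median was 0.41, while those of G2/M (-0.08), S phase (-0.01) and matrix targets (0.11) had the opposite sign, and those of miR-29 targets outside the matrix (-0.13), LNCaP markers (-0.10), epithelial markers (-0.04), mesenchymal markers (-0.0004) and the BCL2 family (0.0008) were nearer to 0. With the mean of both controls, the medians of G2/M genes (0.05), matrix targets (-0.03) and mesenchymal markers (-0.08) lay inside the range of random lists, and those of S phase (0.09) and BCL2 family genes (-0.05) were nearer to 0. Of the named genes, MMP15 was, against siControl, at -0.47, TRAF4 at -0.36, KDM5B at -0.28, BAK1 at -0.22, SLC45A3 at -0.16, ZMAT3 at 0.34 and SLC7A11 at 0.15. Of 27 lists, 14 stood apart against nc, 6 of them in the same direction against siControl, and 9 stood apart between the control arrays and 9 in all against siControl.

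In DU145, miR-29b and nc differed little. No gene reached 2-fold among 9398, and 6 genes were at least 1.5-fold higher and 5 at least 1.5-fold lower, against 15 and 17 between the control arrays. Against siControl 1 gene was at least 2-fold higher and 4 lower, against the mean of both controls 1 was lower, and with no floor 1 was higher and 2 lower. Among protein-coding genes, the largest negative difference was TXNIP (-0.79), followed by TCP11L2 (-0.75) and ZDHHC1 (-0.59), and the largest positive ones were KRTAP10-1 (0.67) and TEX52 (0.64). The miR-29 targets outside the matrix had a median of -0.02 over 31 genes, where matched random lists had -0.04. The matrix targets had a median of -0.12 over 10 genes, where random lists had -0.05, with NID1, a basement membrane protein, at -0.41. Epithelial markers had a median of -0.18, with JUP at -0.42, and mesenchymal markers -0.16, with SNAI2 at -0.41. Lysosome and autophagy genes and genes of the PI3K and mTOR pathway were each at -0.10, hypoxia and glycolysis genes at 0.04 and G2/M genes at 0.02. Cholesterol synthesis genes had a median of -0.16 against nc but 0.23 against siControl. Against siControl, NID1 was at -0.15, JUP at -0.10 and ZDHHC1 at -0.37, and the medians of epithelial markers (-0.07), mesenchymal markers (-0.09), lysosome and autophagy (-0.01) and PI3K and mTOR genes (-0.04) were nearer to 0. With the mean of both controls the epithelial median was -0.05, and with no floor the mesenchymal median was -0.07, both inside the range of random lists. The control arrays of DU145 had as many of 27 lists apart (7) as miR-29b and nc did (7), and 2 of the latter stood apart in the same direction against siControl.

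Over both lines, no gene changed with miR-29b by limma (0 rose and 0 fell among 9209, with 344 at an unadjusted p below 0.05). TET2 differed by -0.41 (SE 0.124) and TET3 by -0.45 (SE 0.132), both with a limma adjusted p of 0.995. Ranked by the smaller of both lines' differences, the lowest genes were LRIG1, a negative regulator of growth factor receptors (-0.48), KDM7A (-0.47), SIPA1L2 (-0.49), TP53INP1 (-0.50) and YPEL2 (-0.43), and the highest was NUPR1 (0.37), with the values of the common fit in brackets. With the preset correlation, limma's camera called 10 of 28 lists, among them miR-29 targets outside the matrix (median -0.12), epithelial markers (-0.11) and mesenchymal markers (-0.12) as lower, and interferon response (0.26) and G2/M genes (0.12) as higher. With an estimated correlation it called 0, with adjusted p = 0.671 for the first 3 and adjusted p = 0.798 for the last 2. In single lines the interferon median against nc was 0.68 in LNCaP and -0.14 in DU145, where the list lay further below siControl. The G2/M median was 0.20 in LNCaP, where it was -0.08 against siControl, and 0.02 in DU145. Adjusted over the list alone, 3 epithelial markers fell, and 0 did over all genes.

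Whether miR-29b and siTET2 moved the same genes was asked within each line, on contrasts that share no array. In LNCaP their differences had a Pearson r of -0.30 and a Spearman rho of -0.29 across 9191 genes, and in DU145 an r of -0.04 and a rho of -0.05 across 9225 genes, which are not independent replicates. With the mean of both control arrays the LNCaP r was 0.03. A shared control with no effect gave 0.333 in a simulation of independent arrays with equal noise. The LNCaP control arrays differed more across genes (SD 0.243) than miR-29b and nc did (SD 0.192), so 0.333 is no exact reference. The DU145 r was -0.35 with the controls exchanged, -0.13 with the stricter floor and 0.09 with no floor. At the same added 1.5-fold threshold, MYBL2 and TET2 were lower with both in LNCaP, 2 genes against 0.510 for independent lists, and CXCL10 and ZMAT3 were higher with both, 2 genes against 0.152. There 9 genes were both among the 50 higher with miR-29b and among the 213 lower with siTET2. Of these, HMMR, APOBEC3B and SLC7A11 were 0.0083, 0.16 and 0.15 from siControl with miR-29b. In turn, 2 genes were lower with miR-29b and higher with siTET2. Of the 32 genes that fell with siTET2 in the common fit, 9 were below 0 with miR-29b in LNCaP and 15 in DU145. Over all genes above the floor, the median with miR-29b was 0.02 in LNCaP and -0.04 in DU145. The 3 that rose with siTET2, YPEL2, TP53INP1 and CD274, were all below 0 with miR-29b in both lines, at -0.43, -0.50 and -0.26 in the common fit. The difference between both effects passed limma's threshold for 0 genes, with 1203 at an unadjusted p below 0.05; with a trend 17 genes passed with a positive and 4 with a negative difference, with the stricter floor 7 with a positive one, and without LNCaP siTET2 14 and 8.

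By gene lists, the difference of effects (miR-29b minus siTET2) in the common fit had a G2/M median of 0.52 and a mesenchymal median of -0.24, both called by limma's camera at the preset correlation, which called 9 of 28 lists. With an estimated correlation it called 0, with adjusted p = 0.498 for G2/M and adjusted p = 0.484 for mesenchymal markers. Genes of DNA methylation and its removal had medians of 0.01 and -0.04 in LNCaP and -0.03 and 0.05 in DU145, for miR-29b and siTET2, inside the range of random lists each time.

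**Figure D4:**
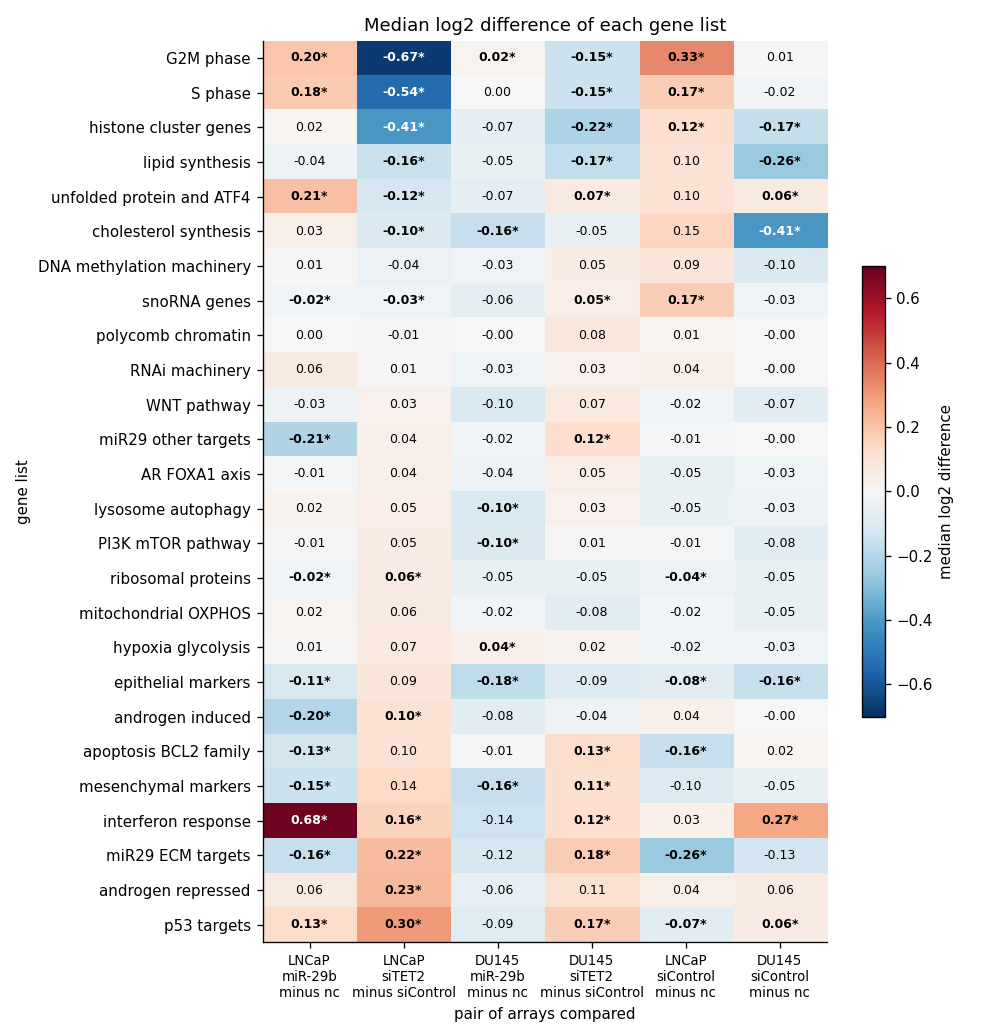
Median log2 difference of the members above the level floor of each gene list (vertical axis) for each pair of arrays compared (horizontal axis), including siControl minus nc in the last 2 columns, with an asterisk where the median stood apart from 10000 random lists. The largest medians are those of interferon response with miR-29b in LNCaP (0.68) and of G2/M (-0.67) and S phase genes (-0.54) with siTET2 in LNCaP.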

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

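The tests below were chosen only after the results were seen, except the loess centring of the LNCaP siTET2 contrast and the search for an exchanged DU145 label by miR-29 targets. Every list and construct here rests on 1 array per group.

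Unfolded protein and ATF4 genes, which respond to endoplasmic reticulum and amino acid stress, drew attention because the siTET2 effect had opposite signs in both lines. Their median was -0.12 in LNCaP and 0.07 in DU145, a gap of -0.18, and each median stood apart from random lists, but against nc the LNCaP median was -0.0091, and against the mean of both controls the DU145 median was 0.04, both inside their range. The snoRNA genes went opposite ways too, with medians of -0.03 and 0.05 and a gap of -0.078. Their direction depends on the setting: in LNCaP the median was 0.17 against nc, 0.066 against the mean of both controls and 0.013 with the stricter floor, and in DU145 it was -0.0069 against nc and -0.017 with no floor. Neither gap was tested, since each line has 1 array per construct.

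Probe sets that the annotation used here does not list were left out of every comparison. In DU145, 12 of them differed at least 2-fold with miR-29b and 18 with siTET2, against 8 between the control arrays.

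Interferon-stimulated genes were higher in the LNCaP miR-29b array. Low values in the nc array alone are argued against, since the list's median was 0.41 against siControl, above every matched random list. Whether there was an equal response to any transfected RNA is not decided. The median excess over the highest of the other 3 LNCaP arrays was 0.16, above every matched random list. However, the pattern was picked because the miR-29b array was high, and some members passed the floor only through that array. An excess of that array was therefore partly built in. A response to this RNA preparation rather than to the miR-29b sequence cannot be told apart from a sequence effect. In DU145 the same construct gave a median of -0.14 against nc, and the list lay further below siControl. From each gene's mean over the line, the medians were -0.22 with miR-29b and 0.13 with siControl. Known miR-29 targets there, however, lay inside the range of random lists (medians of -0.02 outside the matrix and -0.12 in it), which keeps the question open.

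Mitotic genes were lower in the LNCaP siTET2 array. High values in siControl alone are argued against by a median of -0.34 against nc, below every matched random list. An intensity-dependent trend is argued against by the median after loess centring, -0.67, close to the value without it. The growth state of the single dish cannot be told apart from an effect of the siRNA, since the control dishes differed by 0.33 in the same genes. In DU145 the G2/M median was -0.15 with siTET2 (percentile 0.01), and the control dishes differed by 0.006. That line also has 1 dish per construct, so it does not decide the question for the LNCaP dish. A lower rate of division with siTET2 remains a hypothesis that 1 dish per construct leaves untested.

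The miR-29b and nc arrays of DU145 differed in few genes. An exchange of labels with the siTET2 array is argued against by TET2, which was lowest in the array labelled siTET2, -1.18 from the array labelled miR-29b, where the 3 arrays other than siTET2 spanned 0.18. An exchange with nc or siControl cannot be told apart from a weak effect, since no array stood out by low miR-29 targets: set against the mean of the rest, their median was -0.05 in the array labelled miR-29b (percentile 6.52 of random lists) and 0.0016 in the other array with the lowest percentile (10.5). Whether DU145 values are compressed is not settled by the spread across genes, since the contrasts differ. With siTET2 it was 1.04 times that of LNCaP. For siControl minus nc the SD was 0.168 in DU145 and 0.243 in LNCaP, and for miR-29b minus nc 0.136 and 0.192. Weaker or absent repression of miR-29 targets in the array labelled miR-29b remains as a candidate explanation. The median over targets of the LNCaP minus DU145 difference was -0.14, below every matched random list. That value restates the medians of both lines (-0.21 in LNCaP) and is no separate evidence. It also rests on the LNCaP nc array, where the target median was 0.06 against the mean of the rest. Against nc, the DU145 median of targets outside the matrix was -0.02 (percentile 83.1), where random lists had -0.04, so no repression was seen in that contrast. Whether less miR-29b entered the cells was not tested.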

How the results depend on the processing

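The use of nc as the siTET2 control in the common fit, and the 1.5-fold threshold for genes shared between contrasts, were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array; cell line is a term of the common fit. The planned miR-29 seed site analysis was not run, since no 3' UTR sequence was used here. Here a value stayed close if a count lay within 1.5 times of the reported one, a correlation inside its 95% interval across genes, a list median within 1 SD of the medians of its random lists, and a gene's difference within the SD across genes of siControl minus nc in its line; the others moved or turned sign. Among counts and correlations, 172 of the recomputed values stayed close, 73 moved and 3 turned sign; among list medians 550, 178 and 15 did; among differences of named genes 420, 69 and 1 did. A turn of sign was counted for a list only if it had stood apart, and for a gene only if its reported difference was at least 1 in size. Other turns of sign are counted as close or moved. Of the recomputed limma adjusted p-values of the 35 called genes, 118 stayed below the threshold and 79 did not. By these measures, quantile normalization and loess centring left the counts and correlations they were run on close, though with quantile normalization the siTET2 calls of the common fit went from 35 to 27, of which 26 were among the 35. Unless a cause is named, the cause was not tested. The number of arrays and the signal of dim probe sets set the limits here.

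With the line's other control array, genes at least 2-fold higher and lower became 9 and 4 for LNCaP siTET2 (from 5 and 9), lower genes became 1 for LNCaP miR-29b (from 0), higher genes became 20 for DU145 siTET2 (from 12), and 1 and 4 genes passed for DU145 miR-29b (from 0 and 0). Lists apart numbered 9 in place of 14 for each LNCaP contrast. Correlations of miR-29b against siTET2 became -0.33 in LNCaP and -0.35 in DU145 (from -0.30 and -0.04). Between lines they became 0.26 for miR-29b and 0.35 for siTET2 (from 0.09 and 0.39). With LNCaP miR-29b the medians of G2/M (-0.077), S phase (-0.0072), BCL2 family (0.00082), matrix targets (0.11) and ribosomal protein genes (0.014) turned sign. With LNCaP siTET2 those of cholesterol synthesis (0.070) and snoRNA genes (0.17) did, and UGT2B17 (0.28). With DU145 those of cholesterol synthesis for miR-29b (0.23) and snoRNA genes for siTET2 (-0.0069) did. With the mean of both controls, lower genes became 2 for LNCaP siTET2 and 1 for DU145 miR-29b, cholesterol synthesis with DU145 miR-29b turned to 0.063, and snoRNA genes with LNCaP siTET2 to 0.066. The LNCaP correlation of miR-29b and siTET2 turned to 0.030. In a simulation of arrays with equal noise and no effect, sharing a control raised the correlation to 0.333, but the LNCaP arrays need not have equal noise.

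With a 1.5-fold threshold, which admits more genes by construction, higher and lower genes became 57 and 23 (LNCaP miR-29b), 36 and 223 (LNCaP siTET2), 6 and 5 (DU145 miR-29b), and 90 and 150 (DU145 siTET2). With no level floor, which adds dim genes, they became 17 and 1 for LNCaP miR-29b and 1 and 2 for DU145 miR-29b, and lower genes became 15 for LNCaP siTET2. Correlations between treatments became -0.23 in LNCaP and turned sign to 0.089 in DU145 (from -0.04). Between lines they turned sign to -0.14 for miR-29b (from 0.09) and became 0.24 for siTET2. The snoRNA medians turned to 0.039 with LNCaP miR-29b and -0.017 with DU145 siTET2. With the stricter floor, which removes genes, higher genes became 2 (LNCaP miR-29b), 3 (LNCaP siTET2) and 4 (DU145 siTET2). Correlations became -0.13 between treatments in DU145, and 0.24 (miR-29b) and 0.45 (siTET2) between lines. The p53 median with DU145 siTET2 turned to -0.048 and the snoRNA median with LNCaP siTET2 to 0.013. With the mean of a gene's probe sets, TET2 in DU145 siTET2 was -1.08 in place of -1.25.

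In the common fit, siTET2 counts (3 rose and 32 fell) became 17 and 96 with a trend, 11 and 76 with the stricter floor, 0 and 1 with no floor, and 0 and 0 without the term for cell line, which leaves the gap between lines in the spread. With only the 4 arrays of the contrast, 1 rose, and with nc as the control 15 fell; the genes shared with the 35 were 21 of 26 and 15 of 18, and with the stricter floor 22 of 87 and with no floor 0 of 1. The difference of effects gave 17 and 4 with a trend and 7 that rose with the stricter floor, from 0 and 0. Leaving out each array in turn gave 0 to 41 that rose and 0 to 91 that fell for siTET2, and 0 to 14 and 0 to 8 for the difference of effects. Without LNCaP siControl, DU145 siControl or DU145 siTET2 limma called 0 genes for siTET2, without LNCaP siTET2 132 (28 of the 35 among them), without LNCaP nc 10, without either miR-29b array 11 and without DU145 nc 28. Each group has 1 array, so without one of a contrast's arrays its construct is measured in the other line alone. That line's arrays are assumed to vary like the rest. The remaining array of the contrast still enters through the term for cell line. Without LNCaP siControl the TET2 effect was -1.17, where DU145 by itself gave -1.25. The lists called by limma's camera, 10 for miR-29b, 7 for siTET2, 1 for siControl minus nc and 9 for the difference, became 0 each with an estimated correlation and with fry.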

Other observations

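The control arrays of a line differed in named gene groups. In DU145, siControl was higher than nc in MMP1 (1.30), OASL (1.13), CXCL8 (1.09) and IFIT1 (1.08), which were chosen after their values were seen as the 4 genes past 2-fold, and the interferon list had a median of 0.27, above every matched random list. Cholesterol synthesis genes had a median of -0.41 and lipid synthesis genes -0.26 in the same pair, with SCD at -0.93. In LNCaP, siControl was higher than nc in G2/M genes (median 0.33), S phase genes (0.17) and snoRNA genes (0.17), and lower in matrix targets of miR-29 (-0.26) and BCL2 family genes (-0.16). UGT2B17 was 1.34 higher there.

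Among probe sets that the annotation used here does not list, 195 differed at least 2-fold between the control arrays of LNCaP, 187 of them higher with siControl, against 8 in DU145. In the LNCaP contrasts with a treatment the count was 18 for miR-29b and 17 for siTET2.

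Each array's known miR-29 targets outside the matrix were also set against the mean of the other 3 arrays of its line. The median was -0.19 in the LNCaP miR-29b array, below every matched random list, and -0.05 in the DU145 miR-29b array, at percentile 6.52 of matched random lists. It was 0.09 in both siTET2 arrays, and 0.06 in the LNCaP nc array, at percentile 99.6 of matched random lists.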
